A study of Mus musculus with 6 samples.

How the data were processed

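Chromatin immunoprecipitation followed by sequencing (ChIP-seq) with an antibody to estrogen receptor alpha (ERα) was carried out on uteri of ovariectomized mice, which lack their main source of estrogen. The mice carried wild-type ERα or ERα with a mutation in activation function 2 (AF-2), the ligand-dependent activation surface of the receptor's ligand-binding domain. Per the labels' protocols, mice aged 12 weeks received ICI (fulvestrant) or tamoxifen by intraperitoneal injection at 2 mg/kg, or 50 µl of the DMSO vehicle, and uteri were collected after 1 h. The uteri of 6 mice were pooled for each library, so that each of the 6 combinations of genotype and treatment had 1 library. The sample titles also carry the code E1h, which the labels do not explain. It was read as the treatment time of 1 h, since the treatment protocol names only ICI, tamoxifen or DMSO, but an estrogen given beside them is not ruled out by the labels.

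The authors deposited 1 peak list per library. The values in these lists are positions: a chromosome, a start, an end and a name made from them. Each deposited peak was exactly 200 bp wide, which was tested on every list, and the lists carry no height, score, fold enrichment or p-value per peak. Peaks were therefore neither ranked nor filtered by strength, and read depth per library is not given in the sources used here. Per the submitters' processing notes, Bowtie2 2.1.0, SAMtools, Picard, HOMER 4.10.3 and bedtools 2.24.0 were used with the mouse genome build mm9. The notes give no roles, and the peak caller's threshold, any use of an input library and any filter on regions are not given in the sources used here. These choices set how many peaks a list holds, as does the depth of a library. A difference in peak number can therefore come from the library as well as from the receptor.

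From the deposited lists, overlaps were computed with Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1). A peak counted as shared when it overlapped a peak of the other list by at least 1 bp. All 30 overlap counts were checked against bedtools 2.31.1 and 0 differed. As a chance level, the peaks of one list were shifted around each chromosome 1000 times by random distances, which keeps their spacing. These shifts used chromosomes 1 to 19 and X and the last peak end of any list as the chromosome's end. Shares of peaks are given with exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only, not the variation between mice or libraries. Peaks of the 6 lists were merged to regions wherever they overlapped by 1 bp. Windows of 100 kb were laid end to end from the start of each chromosome, and a peak was assigned to the window of its midpoint. Simulated lists were made from the wild-type ICI peaks, with shared peaks set to between 20% and 80%. The largest error of a recovered share was 0.00302 percentage points. Simulated shared peaks overlapped by construction and the others could not, so this checks the counting only.

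With 1 library per group there is no spread between replicates. Every comparison is between libraries. The only p-value is from an exact permutation of the vehicle label within genotypes, chosen after the peak numbers were seen. Its statistic averages the excess of the ligand lists over vehicle across the genotypes. Regions were named by a rule set before the data were examined: the 3 windows of 100 kb with the most peaks in each list, and the 3 highest-scoring peaks of each list and of each ligand's genotype-specific peaks. Lacking scores, that rule passed to the widest peaks and, all widths being equal, to the first peaks along chromosome 1. Windows chosen after their values were seen are identified as such. The alternatives set before the data were examined were a different overlap, lists of equal length, merging of neighbouring peaks, restriction to chromosomes 1 to 19 and X, and a shift over 10 to 50 kb only. The planned comparisons by position relative to genes, by gene list and by estrogen response element needed an annotation or sequence of mm9, which was not used here. The gene table at hand was of another build, GRCm38, and coordinates were not converted. Peak density per chromosome was given in their place, as set before the data were examined, and genes are not named. The planned comparison of scores was also left out.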

Results

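ERα binding was mapped by ChIP-seq in the uterus of ovariectomized wild-type and ERα AF-2 mutant mice 1 h after ICI, tamoxifen or vehicle, as the treatment protocol describes the groups; the sample titles carry a further code, E1h, that the labels do not explain. ICI (fulvestrant) is a steroid-based ERα antagonist that also promotes loss of the receptor. Tamoxifen is a nonsteroidal triphenylethylene that acts as agonist or antagonist depending on the tissue. Both were given at 2 mg/kg. AF-2 is the surface through which ligand-bound ERα recruits coactivators, and in AF-2 mutant mice compounds classed as antagonists are known to act as agonists in some tissues. The comparisons ask where each ligand placed the receptor on the genome, and whether the AF-2 mutation changed this. Each of the 6 groups was 1 library from a pool of 6 uteri. All coordinates are in mm9 and count from 1, and read depth is unknown.

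With either ligand, ERα occupied several times as many called sites as with vehicle in both genotypes. The wild-type uterus had 3712 peaks with vehicle, 26482 with ICI and 37327 with tamoxifen. The AF-2 mutant uterus had 5027 peaks with vehicle, 45837 with ICI and 36538 with tamoxifen. Relative to vehicle, ICI gave 7.13 times as many peaks in the wild type (95% counting interval 6.89 to 7.39) and 9.12 times as many in the mutant (8.86 to 9.39). Tamoxifen gave 10.1 times as many in the wild type (9.72 to 10.4) and 7.27 times as many in the mutant (7.06 to 7.49). The intervals cover counting error only. Within each genotype, the mean log2 peak number of the ligand lists exceeded that of vehicle by 3.08 in the wild type and 3.03 in the mutant. These means average over unlike ligands: the excess was 2.83 and 3.19 for ICI, and 3.33 and 2.86 for tamoxifen, in the same order. With the genotypes as blocks, an exact permutation test of the vehicle label (two-sided, 9 arrangements) gave p = 0.111, the smallest that these arrangements can give. The test was chosen after the peak numbers were seen. Vehicle was by far the lowest in both genotypes, so this outcome was already set and adds nothing to the counts. An additive model of genotype and treatment assumes the same ligand effect in both genotypes. It left a residual SD of 0.292 on the log2 scale with 2 residual degrees of freedom, and no test was based on it. No other difference in peak number was tested.

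**Figure D1:**
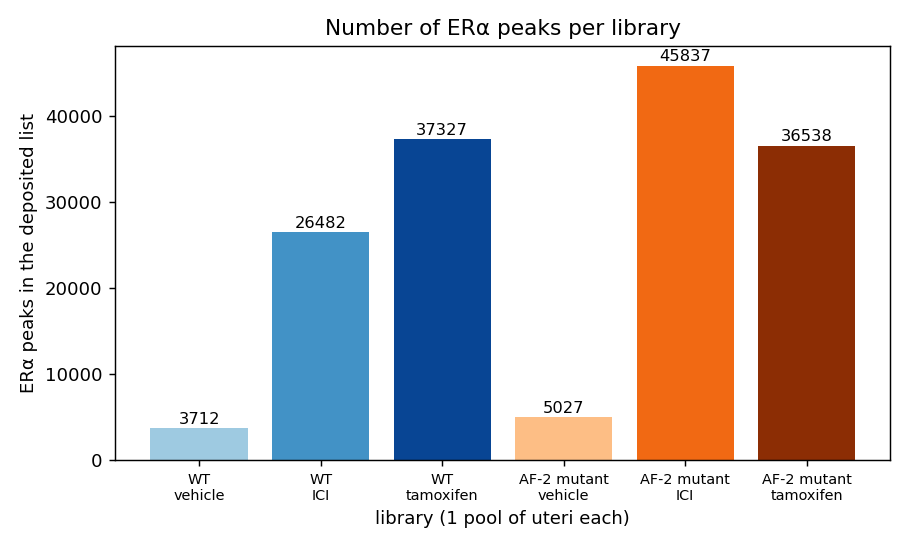
Number of ERα peaks (y axis) in each of the 6 deposited lists (x axis, 1 library per bar, no error bars because each group is a single pool). The vehicle bars stand at 3712 and 5027 peaks, and the ligand bars at 26482 to 45837.

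The order of the ligands differed between genotypes. ICI gave fewer peaks than tamoxifen in the wild type, at a ratio of 0.709 (0.698 to 0.721), and more than tamoxifen in the mutant, at a ratio of 1.25 (1.24 to 1.27). Between genotypes, the mutant had 1.73 times the wild-type number of peaks with ICI (1.70 to 1.76), 0.979 times with tamoxifen (0.965 to 0.993) and 1.35 times with vehicle (1.30 to 1.41). The genotypes thus differed most in peak number under ICI and least under tamoxifen.

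Most sites bound under vehicle were also bound after ligand. In the wild type, 67.4% of vehicle peaks overlapped an ICI peak (95% interval 65.8 to 68.9) and 78.9% a tamoxifen peak (77.6 to 80.2). In the mutant the shares were 61.2% for ICI (59.8 to 62.5) and 62.0% for tamoxifen (60.6 to 63.3). Shifted lists gave mean shares of 0.425%, 0.591%, 0.731% and 0.584% in the same order. Counting all 4 ligand lists of both genotypes, 89.1% of wild-type vehicle peaks (88.1 to 90.1) and 74.1% of mutant vehicle peaks (72.9 to 75.3) lay at a ligand-bound site. An example is the site on chromosome 1 at 7145113 to 7145312, the first wild-type vehicle peak, which was also called in all 4 ligand lists.

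The converse shares could only be small, since the vehicle lists held 3712 and 5027 peaks and the ligand lists 26482 to 45837. Of wild-type peaks, 9.44% with ICI (9.09 to 9.80) and 7.85% with tamoxifen (7.58 to 8.13) overlapped a wild-type vehicle peak. Of mutant peaks, 6.71% with ICI (6.48 to 6.94) and 8.53% with tamoxifen (8.24 to 8.82) overlapped a mutant vehicle peak. The peaks without a vehicle counterpart numbered 23981 with ICI and 34397 with tamoxifen in the wild type, and 42761 with ICI and 33423 with tamoxifen in the mutant. The lists do not show signal below the authors' threshold, so absence from a vehicle list is not absence of binding.

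The vehicle lists of the genotypes overlapped each other at lower shares than any pair of ligand lists did, for which the shares ran from 42.0% to 85.6%. Shares depend on list length, however, and the vehicle lists are much shorter, so the order of the shares says little about the sites. Of the wild-type vehicle peaks, 29.4% overlapped a mutant vehicle peak (27.98 to 30.94), and of the mutant vehicle peaks 21.7% overlapped a wild-type one (20.6 to 22.9). Mean chance shares were 0.0797% and 0.0574% with shifts around the chromosome, and 0.161% and 0.116% with shifts by 10 to 50 kb. Wild-type vehicle peaks overlapped the mutant ICI list at 77.4% (76.0 to 78.8) and the mutant tamoxifen list at 76.2% (74.8 to 77.6). Mutant vehicle peaks overlapped the wild-type ICI list at 33.7% (32.4 to 35.0) and the wild-type tamoxifen list at 43.9% (42.5 to 45.3). The window with the most wild-type vehicle peaks, on chromosome 5 at 120000001 to 120100000, held 6 of them and 5 mutant vehicle peaks. Mutant vehicle peaks were densest on chromosome 11 at 35000001 to 35100000 and on chromosome X at 96600001 to 96700000, with 6 peaks in each window against 1 wild-type vehicle peak in each.

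**Figure D2:**
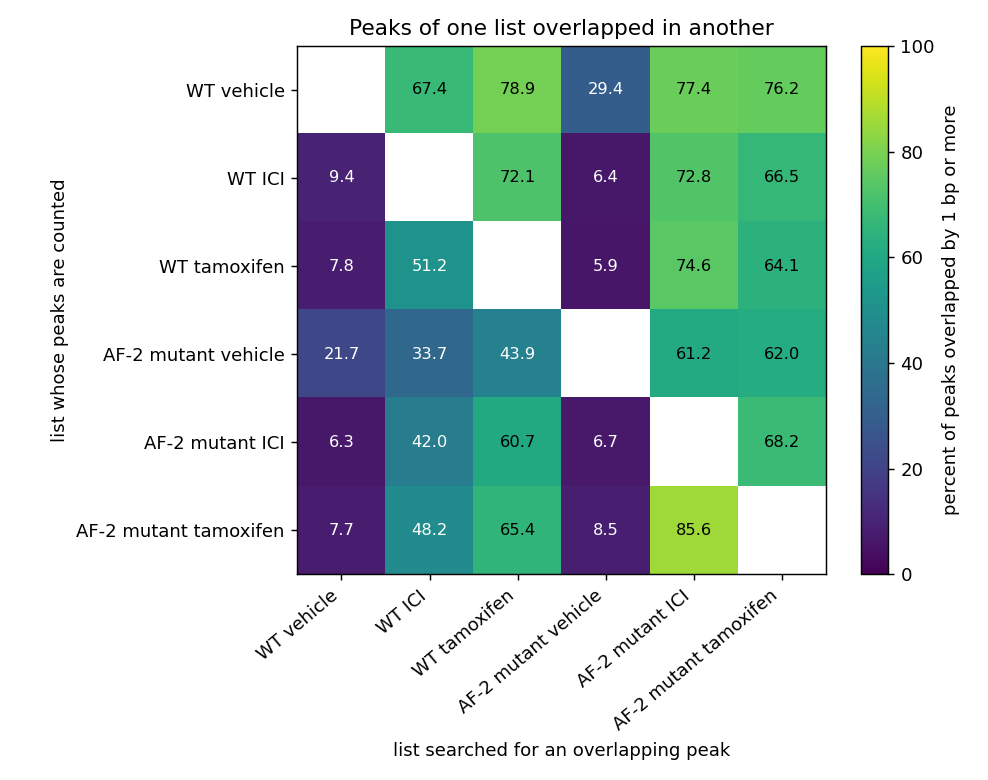
Percent of the peaks of each list (rows) that overlap a peak of another list (columns) by at least 1 bp, on a colour scale from 0 to 100. The mutant tamoxifen row reaches 85.6% in the mutant ICI column, while the vehicle lists overlap each other at 29.4% and 21.7%.

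ICI and tamoxifen, compared at the same dose and time, had largely overlapping peaks in lists of different length. In the mutant, 85.6% of tamoxifen peaks overlapped an ICI peak (85.2 to 85.9), and 68.2% of ICI peaks overlapped a tamoxifen peak (67.8 to 68.6). In the wild type, 72.1% of ICI peaks overlapped a tamoxifen peak (71.6 to 72.7), and 51.2% of tamoxifen peaks overlapped an ICI peak (50.7 to 51.7). Mean chance shares lay between 0.420% and 0.727%. Each ligand also had peaks that the other lacked: 7378 with ICI and 18222 with tamoxifen in the wild type, and 14567 with ICI and 5267 with tamoxifen in the mutant.

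One of several windows tied for the largest excess of wild-type tamoxifen over wild-type ICI peaks lay on chromosome 1 at 93700001 to 93800000, chosen after the values were seen. It held 15 tamoxifen peaks and 6 ICI peaks in the wild type, and 14 peaks with each ligand in the mutant. In another of the tied windows, on chromosome 7 at 140900001 to 141000000, wild-type tamoxifen gave 13 peaks and wild-type ICI 4, and the mutant gave 4 with ICI and 2 with tamoxifen. This second window was also chosen afterwards.

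Between genotypes, the ICI lists differed in length, and so did the shares of each that overlapped the other. Of wild-type ICI peaks, 72.8% overlapped a mutant ICI peak (72.2 to 73.3), whereas 42.0% of mutant ICI peaks overlapped a wild-type one (41.6 to 42.5), leaving 26565 mutant ICI peaks without a counterpart. With the mutant ICI list thinned at random to the wild-type length, 42.1% of wild-type ICI peaks overlapped it, lower by construction. For tamoxifen the shares were nearly symmetrical, with 65.4% of mutant peaks in the wild type (65.0 to 65.9) and 64.1% of wild-type peaks in the mutant (63.6 to 64.6). Mean chance shares for these 4 values lay between 0.421% and 0.727%.

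Many wild-type tamoxifen peaks absent from the wild-type ICI list were in the mutant ICI list, at a lower share than all wild-type tamoxifen peaks (74.6%). Wild-type ICI was the shortest ligand list. Mutant ICI was the longest, with 45837 peaks against 36538 for mutant tamoxifen. Absence from a list is not absence of binding. Of the 18222 wild-type tamoxifen peaks without a wild-type ICI peak, 61.3% overlapped a mutant ICI peak (60.6 to 62.1) and 46.1% a mutant tamoxifen peak (45.4 to 46.8). Mean chance shares were 0.725% and 0.583%. For wild-type tamoxifen peaks that did have a wild-type ICI peak, the shares were 87.2% (86.7 to 87.7) and 81.2% (80.6 to 81.7). Conversely, of the 26565 mutant ICI peaks without a wild-type ICI peak, 42.1% overlapped a wild-type tamoxifen peak (41.6 to 42.7). Of the 19272 mutant ICI peaks with one, 86.3% did (85.9 to 86.8).

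Merging the 6 lists gave 65146 regions, of which 63548 held a ligand peak. A core of 15144 regions, 23.8% of those with a ligand peak, was held by all 4 ligand lists, and 12151 of these were in neither vehicle list. With the 3 longer ligand lists thinned at random to the length of the wild-type ICI list, these fell to 4503 and 3611 (means of 100 draws). Regions held by 1 ligand list only numbered 8430 for mutant ICI, 6298 for wild-type tamoxifen, 4228 for wild-type ICI and 3569 for mutant tamoxifen. In the thinned lists they numbered 6910, 6290, 6300 and 5538 in the same order. A further 7644 regions were held by every ligand list except wild-type ICI, against 442 missing only from mutant ICI. In the thinned lists this order turned, to 2269 against 3511. By genotype, 32142 regions were held by a ligand list of each genotype, 18904 by ligand lists of the mutant alone and 12502 by ligand lists of the wild type alone. Vehicle lists were not considered in these counts, and some of the regions held a vehicle peak of the other genotype. Without the wild-type ICI list, the regions held by all remaining ligand lists numbered 22788 and those of the wild type alone 8274. With lists thinned to equal length, the mutant and the wild type alone held 16274 and 15801 regions on average. Thinning removes peaks at random, and by construction it moves regions into combinations of fewer lists, while the wild-type ICI list stays whole.

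Among regions held by exactly 2 ligand lists, pairs of the same genotype and pairs of the same ligand differed in number. Mutant ICI and mutant tamoxifen alone shared 6905 regions, and wild-type ICI and wild-type tamoxifen alone shared 1976. ICI in both genotypes without tamoxifen gave 989 regions, and tamoxifen in both genotypes without ICI gave 725. The mixed pairs gave 3495 regions for wild-type tamoxifen with mutant ICI and 481 for wild-type ICI with mutant tamoxifen. With lists thinned in the same way, the pairs of the same genotype held 3827 in the mutant and 3211 in the wild type. Those of the same ligand then held 1796 for ICI and 2035 for tamoxifen, below the 2297 and 2283 of the mixed pairs. By construction, thinning moves regions held by more lists into these pairs, so the thinned order says nothing about the pairs as deposited.

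**Figure D3:**
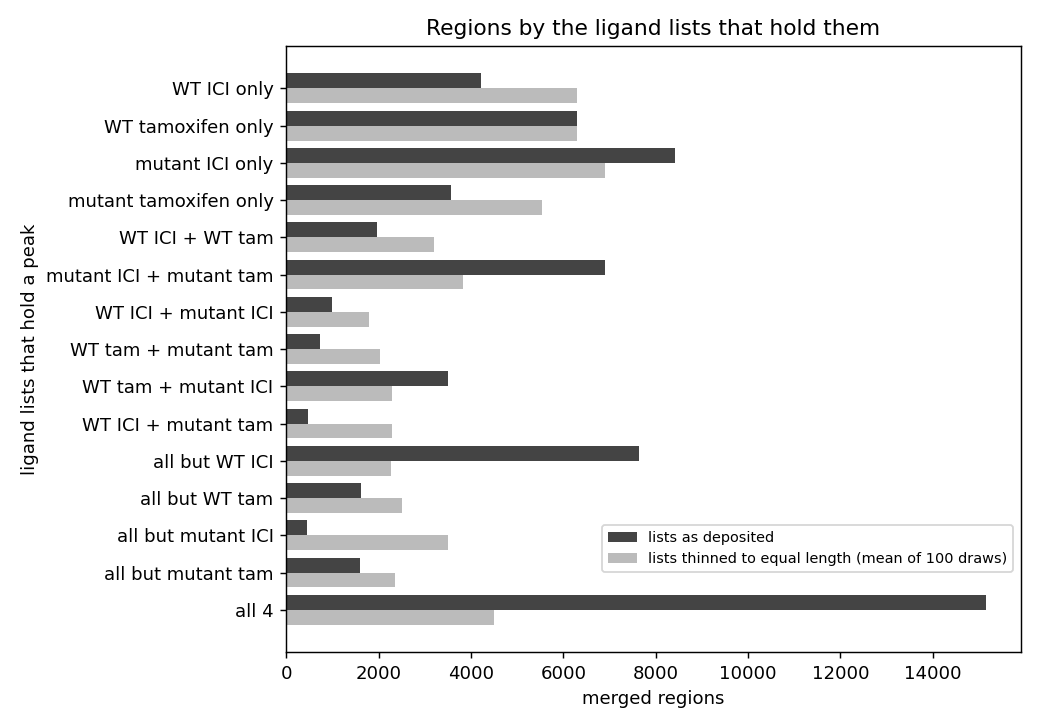
Number of merged regions (x axis) held by each combination of the 4 ligand lists (y axis), for the lists as deposited (dark bars) and thinned to equal length (light bars, means of 100 draws). The combination of all 4 lists is the longest dark bar, at 15144 regions. Among the pairs as deposited, those of the same genotype hold 6905 and 1976 regions and those of the same ligand 989 and 725. The mixed pairs hold 3495 and 481. The light bars of the pairs also count regions of more lists that lost peaks by thinning.

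ERα peaks were unevenly spread and formed dense windows. The densest windows of the mutant ICI list lay on chromosome 14 at 26300001 to 26400000 with 23 peaks, on chromosome 1 at 74000001 to 74100000 with 22, and on chromosome 4 at 149200001 to 149300000 with 22. The wild-type ICI list had 11, 10 and 9 peaks in these windows, and the wild-type tamoxifen list 18, 13 and 14. For mutant tamoxifen the densest was on chromosome 8 at 122500001 to 122600000, with 21 peaks there against 17 for wild-type tamoxifen. On the same chromosome, wild-type tamoxifen was densest at 122800001 to 122900000 with 20 peaks, and wild-type ICI at 122900001 to 123000000 with 13. Wild-type ICI also had 13 peaks on chromosome 10 at 76100001 to 76200000, where the other ligand lists had 11 to 13 and the vehicle lists 0. Further dense windows of wild-type tamoxifen were on chromosome 5 at 114000001 to 114100000 with 19 peaks and at 125500001 to 125600000 with 18. Wild-type vehicle had 4 peaks in several windows, among them those on chromosome 2 at 154500001 to 154600000 and on chromosome 5 at 124400001 to 124500000. One window, on chromosome 1 at 75300001 to 75400000, was among the densest of both wild-type ICI (12 peaks) and mutant vehicle (5 peaks).

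In the chromosome 4 window, all 9 wild-type ICI peaks overlapped a peak in each of the other 3 ligand lists, and all 14 wild-type tamoxifen peaks overlapped a peak in both mutant ligand lists. Mutant ICI and mutant tamoxifen had 22 and 20 peaks there, of which 19 were shared. The wild-type vehicle list had 0 peaks in the window and the mutant vehicle list 2. This window was also among those tied for the largest excess of mutant over wild-type ICI peaks. Its full overlap was not typical. In the whole lists, 72.8% of wild-type ICI peaks overlapped a mutant ICI peak and 72.1% a wild-type tamoxifen peak. Of wild-type tamoxifen peaks, 64.1% overlapped a mutant tamoxifen peak.

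**Figure D4:**
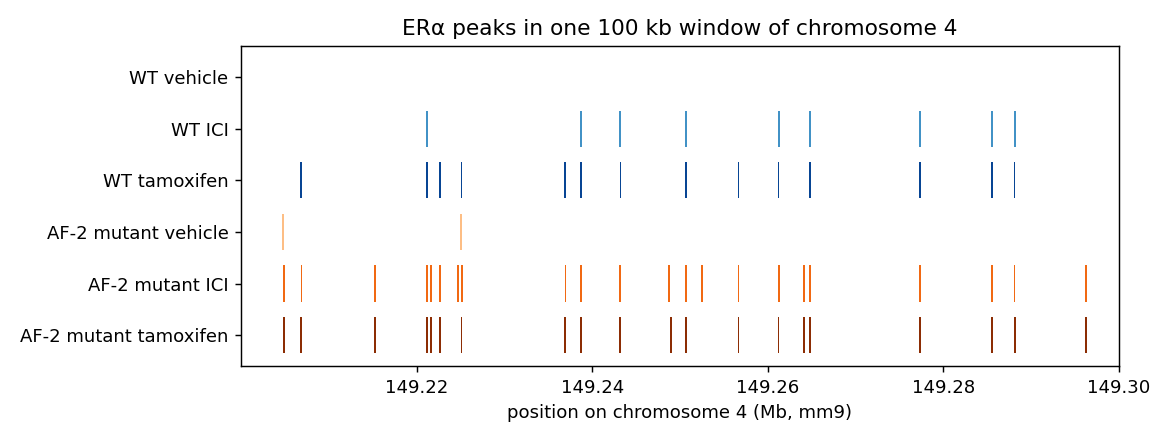
ERα peaks (200 bp bars drawn to scale) along chromosome 4 from 149200001 to 149300000 (x axis in Mb, mm9) in the 6 lists (rows). Wild-type ICI has 9 peaks, wild-type tamoxifen 14, mutant tamoxifen 20 and mutant ICI 22. Each of the 9 wild-type ICI positions recurs in the other 3 ligand rows. In the whole lists, 72.8% of wild-type ICI peaks overlapped a mutant ICI peak.

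Windows that set the genotypes apart were looked for after the values were seen. One of several windows tied for the largest excess of mutant over wild-type ICI peaks lay on chromosome 2 at 105000001 to 105100000, with 17 peaks against 4, where mutant tamoxifen had 13 and wild-type tamoxifen 10. Mutant tamoxifen exceeded wild-type tamoxifen most on chromosome 2 at 169500001 to 169600000, with 12 peaks against 3, where mutant ICI had 10 and wild-type ICI 1. In the opposite direction, on chromosome 4 at 136500001 to 136600000, the wild type had 6 peaks with each ligand and the mutant 1 with each. These are among the extremes of 16110 windows with a peak in any list, and no replicate shows how much such counts vary.

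Single sites illustrate the classes. These are the first along chromosome 1 under the naming rule and were not picked for strength. The site at 3349947 to 3350146 was called in all 4 ligand lists and in no vehicle list. The peak at 4218752 to 4218951 was called with ICI and tamoxifen in the mutant and in no wild-type list. The peak at 4966597 to 4966796 was called with both ligands in the wild type and in no mutant list. That at 3903885 to 3904084 was called with mutant ICI and wild-type tamoxifen, and that at 3194177 to 3194376 with wild-type ICI alone.

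Peak density was lowest on the X chromosome in all 6 lists. Among the autosomes, chromosome 11 was highest and 3 lowest in all lists except wild-type vehicle, where 8 was highest and 14 lowest. Mutant ICI peaks had a density of 18.2 per Mb over the autosomes, from 14.2 on chromosome 3 to 25.4 on chromosome 11, and of 5.56 per Mb on the X chromosome. In the wild type with ICI the autosomal and X densities were 10.5 and 3.20 per Mb. With tamoxifen they were 14.8 and 4.27 in the wild type and 14.5 and 4.70 in the mutant. The X chromosome held 2.02% of mutant ICI peaks (1.89 to 2.15) and 2.14% of mutant tamoxifen peaks (2.00 to 2.30), and 2.80% of mutant vehicle peaks (2.37 to 3.30). In the wild type it held 2.01% of ICI peaks (1.85 to 2.19), 1.90% of tamoxifen peaks (1.77 to 2.05) and 2.48% of vehicle peaks (2.00 to 3.03).

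**Figure D5:**
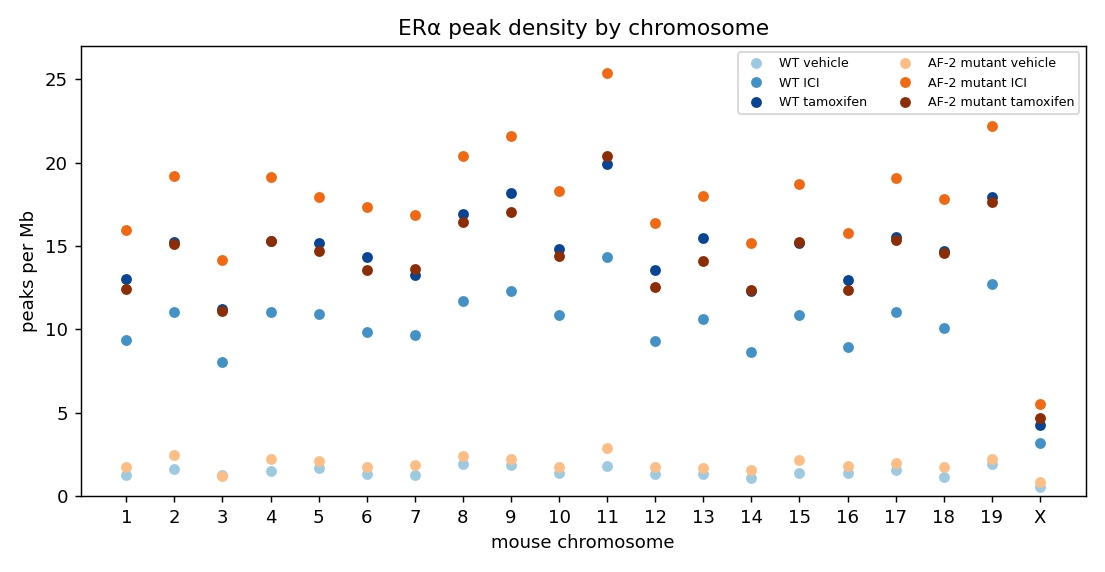
ERα peaks per Mb (y axis) on each mouse chromosome (x axis) in the 6 lists (colours, 1 point per library). Mutant ICI is highest on every chromosome, reaching 25.4 on chromosome 11, and every list is lowest on the X chromosome.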

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

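The tests in this part were chosen after the peak numbers and overlaps had been seen, except the ratio of midpoint distances, which was set before its result was known.

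The ligands took opposite orders in the genotypes: the ratio of ICI to tamoxifen peak numbers was 1.25 in the mutant and 0.709 in the wild type. The difference was not tested, since each value comes from 1 library. A different response of the mutant receptor to ICI and a lower sensitivity of the wild-type ICI library both stay open. Of the mutant ICI peaks that the wild-type ICI list lacked, 42.1% were wild-type tamoxifen sites, which either could give, and without depths or peak heights these cannot be told apart.

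The vehicle lists of the genotypes shared 29.4% of the wild-type and 21.7% of the mutant list, in lists much shorter than the ligand lists. These shares were 370 and 378 times their mean chance shares, the highest of any pair of lists. Between ligand lists the multiples ran from 99.9 to 122. A share and its multiple of chance both depend on list length, so neither shows whether the sharing was unusual. Randomly placed false peaks as the source of all the unshared peaks are argued against. Of the unshared mutant vehicle peaks 69.5% (68.1 to 71.0) lay at ligand sites, and of the unshared wild-type ones 88.4% (87.1 to 89.6). Mean chance shares were 1.05% for each. The remaining 1198 mutant and 304 wild-type unshared peaks lay in no ligand list and could include such false peaks. False peaks that recur at the same place in several libraries would also overlap ligand lists, so they stay open. Peaks called beside each other, rather than on each other, are argued against as the main cause up to 500 bp: of the unshared wild-type vehicle peaks only 1.41% (1.00 to 1.94) had a mutant vehicle midpoint within 500 bp, and of the unshared mutant ones 0.915% (0.642 to 1.26) had a wild-type one. The median midpoint distance of mutant vehicle peaks to mutant ICI peaks within 500 bp was 31 bp, against 21 bp for the wild-type pair. The ratio of 1.48 lay between the limits of 1.2 and 1.5 set beforehand. Its range of 1.32 to 1.66, formed from the ends of both medians' bootstrap intervals, passed the upper limit. This ratio therefore could not decide whether mutant vehicle peaks were centred beside the ligand peaks. Short list length, weak calls near the peak caller's threshold and a genotype difference in binding under vehicle also stay open, as untested.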

How the results depend on the processing

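Of 124 alternative values, 67 stayed within their counting interval, within the range of shifts or, for counts, within 1.5 times the main value, and 57 moved further. Most of these values are counts or shares with no direction of their own, but under thinning some orders between them turned. Thinning moves regions into combinations of fewer lists by construction, while the wild-type ICI list stays whole. Those turns therefore cannot show whether the orders in the whole lists are stable. Thinning to equal length and leaving out a list, for regions, the other overlaps of conditional sets, and merging for the X chromosome share were added after the data were seen. Restricting to chromosomes 1 to 19 and X moved none of 16 values. It could hardly do so, since only 0 to 21 peaks per list lay elsewhere. The 124 values also count the wild-type ratio of ICI to tamoxifen peak numbers together with its reciprocal. Merging peaks within 500 bp moved the ratios to vehicle to 8.67 for mutant ICI, 6.97 for mutant tamoxifen and 9.67 for wild-type tamoxifen, and the mutant to wild-type ratio for ICI to 1.68. Requiring an overlap of 100 bp of the 200 bp gave, for vehicle peaks, 62.6% in ICI and 76.3% in tamoxifen in the wild type, 54.7% and 55.8% in the mutant, and 27.8% of wild-type in mutant vehicle. It gave 70.1% of wild-type ICI in tamoxifen, 84.5% of mutant tamoxifen in ICI, 70.6% of wild-type in mutant ICI and 64.7% of mutant in wild-type tamoxifen. Vehicle peaks at any ligand site were then 86.4% in the wild type and 68.6% in the mutant, and wild-type tamoxifen peaks without ICI lay in mutant ICI at 60.6%. Midpoints within 500 bp gave, in the order of the vehicle and ligand pairs above, 72.5%, 81.8%, 67.2% and 67.5%, then 74.4%, 86.9%, 75.4% and 67.2%. They gave 92.2% and 79.7% for vehicle peaks at any ligand site, and 43.0% for mutant ICI peaks without wild-type ICI in wild-type tamoxifen. Thinning the longer list to the length of the shorter lowered the share by construction, to 9.35%, 7.81%, 6.78%, 8.53% and 21.8% for the vehicle pairs and to 51.2%, 68.2%, 42.1% and 64.1% for the ligand pairs. Shifts by 10 to 50 kb gave mean chance shares of 0.871%, 1.56% and 1.28% (wild-type vehicle in ICI, mutant vehicle in ICI and in tamoxifen) and 1.35%, 1.79%, 1.66% and 1.38% for the ligand pairs. With the longer ligand lists thinned to the length of wild-type ICI, which removes peaks at random, 4503 regions were in all 4, 3611 of them in no vehicle list, 2269 in all but wild-type ICI, 3511 in all but mutant ICI (7644 and 442 in the whole lists) and 5538 in mutant tamoxifen only. Pairs alone then held 3827 (mutant), 3211 (wild type), 1796 (ICI), 2035 (tamoxifen), 2297 (wild-type tamoxifen with mutant ICI) and 2283 (wild-type ICI with mutant tamoxifen), so that the same-ligand pairs, 989 and 725 against 481 for the last pair in the whole lists, fell below it. Without the mutant vehicle list, regions with vehicle peaks only fell from 1598 to 400. Without the wild-type ICI list, 22788 regions were in all remaining ligand lists and 8274 in wild-type tamoxifen but no mutant ligand list. The cause of the other moves was not tested. Score thresholds, gene positions, gene lists and response elements were not run, and with 1 library per group no replicate could be left out. No analysis with a replicate block was run, since each group has 1 library and the labels give no replicate numbers; the only blocked comparison took the genotypes as blocks for the peak numbers.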

Other observations

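The test on the X chromosome was set before its result was seen, and the other values were computed without a prediction.

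ERα peaks lay close together more often than uniform placement would give. In the mutant ICI list 60.6% of peaks had another within 10 kb, against 30.4% for uniformly placed peaks, and in the wild-type ICI list 43.0% did, against 18.9%. For vehicle the shares were 11.6% in the mutant and 6.95% in the wild type, against 3.93% and 2.94%. Regions held by all 4 ligand lists had another such region within 10 kb in 32.9% of cases (32.2 to 33.7). Regions held by 1 ligand list only, with or without a vehicle peak, lay within 10 kb of one in 23.9% (23.4 to 24.5), and regions seen in 1 or both vehicle lists only in 28.7% (26.5 to 31.0), against mean chance shares of 9.91% and 9.90%.

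Peaks at shared sites were placed close to each other between libraries. The median midpoint distance of peaks within 500 bp of each other was 12 bp between mutant and wild-type tamoxifen, 13 bp between the mutant's ligand lists and 18 bp between the ICI lists. It was largest between mutant vehicle and wild-type ICI, at 61 bp, where 18.7% of the pairs were 200 bp or more apart. On chromosome 1, for example, the first mutant vehicle peak at 4416945 to 4417144 overlapped no other list, although a mutant ICI peak lay beside it at 4416679 to 4416878.

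The X chromosome held fewer peaks per Mb than the autosomes, at 0.288 to 0.325 of the autosomal density in the ligand lists and 0.377 and 0.428 in the wild-type and mutant vehicle lists. Long stretches without any peak, such as sequence in which reads cannot be placed, could lower the X density. Of the X chromosome's 1 Mb windows 76.0% held a peak of any list, against 91.4% on the autosomes. Within such windows the highest X to autosome ratio among the ligand lists was still 0.391 (0.365 to 0.420). The range covers the counting error of the X peaks only. The ratio lay under the limit of 0.6 set beforehand, which argues against such stretches as the whole cause. Gene content and finer differences in mappability stay open as untested.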
